A study of Acetivibrio thermocellus DSM 1313 with 36 samples.

How the data were processed

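The data are RNA sequencing libraries of Clostridium thermocellum DSM1313. Per the labels' protocols, 4 strains (the parent and 3 strains with 1 more regulator gene deleted) were grown in pH-controlled bioreactors in MTC medium at 58 °C and 100 rpm with 5 g/L cellobiose, each in triplicate. Samples of 50 ml were taken at 3 growth phases, and cells were lysed in TRIzol by bead beating. Ribosomal RNA was removed with a Ribo-Zero kit for Gram-positive bacteria, libraries were made with the ScriptSeq kit, and they were pooled into 3 groups for single-end sequencing on an Illumina HiSeq instrument, per the labels' protocols. Which library was in which pool is not given in the sources used here. The library codes run in 3 unbroken blocks of 12, 1 block per replicate number with every strain and phase in it, and whether these blocks are the pools is not stated. The fits with the replicate number as a block remove a constant difference between these blocks. The submitters' processing notes name bcl2fastq 1.8.3 and DESeq2. The aligner, the counting tool, the genome build, the annotation and the use of strand are not given in the sources used here. Genes that share reads with a near-identical copy, or that overlap, are therefore uncertain.

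The deposited table holds whole-number read counts per gene, not normalized by the authors as far as the values show: the counts are integers and their totals differ between libraries. It has 3103 rows, of which 3031 carry a numbered locus, 69 carry an R-numbered locus and 3 carry the names ssrA, rnpB and ffs. Columns were matched to samples through the library code in the sample description, and no column was left without a sample. The R-numbered rows were kept out of library sizes and tests, under a choice made before the data were examined to leave out ribosomal and transfer RNA. They took 0.170% to 1.16% of the reads of a library (median 0.453%), and the files do not say what each of them holds. The most abundant gene took 4.01% to 13.5% of a library's reads, and ssrA 0.685% to 4.31%. Totals were 11067095 to 27329402 reads per library (median 18130811), and at these depths the spread between fermentations, not counting error, sets the precision of all but the rarest transcripts. Replicate libraries were compared by a chi-square test of their counts: all 36 pairs differed by more than sampling noise (chi-square per degree of freedom 31.5 to 296), and no pair was identical.

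Groups are the 12 combinations of strain and phase, taken from the strain and time point labels, with the replicate number from the title. Differences were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM library scaling and filterByExpr on the 12 groups, which left 2977 genes. A model with 1 mean per group was fitted to all 36 libraries, so that all groups share the estimate of the spread. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p below 0.05. The comparisons were each deletion strain against the parent at each phase, the successive phases of the parent, and, for each strain, a test with both phase differences together of whether its effect changed with phase. The standard error printed beside a log2 fold change is its size divided by the square root of the F statistic, and is approximate. CPM values use TMM-scaled library sizes. The libraries of a group come from separate fermentations, and p-values set each difference against the spread between them, estimated over all 12 groups. Each deletion is represented by 1 strain, so any other difference of that strain from the parent cannot be told from an effect of the deletion.

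Genes named in the text follow a rule set before the data were examined. It takes the deleted genes, the loci within 5 of them, the largest increases and decreases of each comparison among called genes whose 3 libraries all lay on the same side of the 3 others and whose mean was at least 10 CPM in 1 of the groups, the genes called at all 3 phases with the smallest p, and the genes with the smallest interaction p. Since the files pair no gene names with the loci, at most 2 loci that rose and 2 that fell are given per comparison. The 3 named small RNAs are given where they were called. The rule also named hpt, whose locus the sources used here do not give, so that it is not reported. Of the gene lists fixed before the data were examined, 25 were defined by words of product descriptions and could not be tested for the same reason. The 3 neighbourhood lists, each with 10 members, were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and, as an alternative, an estimated one, adjusted over 33 tests. The self-contained test fry was run beside it in either direction, and 20 of the 33 tests had an adjusted p below 0.05. Runs are at least 3 consecutive loci that were called in the same direction and changed at least 2-fold.

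Each replicate number occurs in every group. For the comparisons of phases the same number was taken as the same fermenter, since the protocol describes samples of each fermenter at 3 phases. For the comparisons of strains the numbers were checked by the correlation of same-numbered libraries' deviations from their group means. It was above 0.1 for all 3 pairs only at stationary phase in del0089 (0.146 to 0.374) and del0396 (0.112 to 0.454) against the parent.

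Alternatives chosen before the data were examined were DESeq2 size factors, the test of DESeq2 1.42.0, no filter on low counts, the R-numbered rows kept, counts thinned to the smallest library, a minimum change of 2-fold, the replicate number as a block, only the 6 libraries compared, and each library left out in turn. Added after the data were seen were fits without 2 mid-exponential libraries that stood apart and the fermenter as a block in the interaction tests. Also added were the runs and neighbourhood lists without mid-exponential parent replicate 2 and the run medians and strain overlaps with single libraries left out. Covariances and correlations between strains were set beside those of 20 simulated sets of unchanged groups against shared parent libraries. Figures were drawn with matplotlib 3.10.9.

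The tests were tried on simulated counts for the comparison of del0089 with the parent at mid-exponential growth, with 2977 genes. Of 50 genes seeded at each size, 31 were recovered at 1.5-fold, 44 at 2-fold, 50 at 4-fold and 50 at 8-fold, with 3 false calls among 178. The interaction test recovered 17, 35, 50 and 49 of them. A comparison with no seeded change, that of del0396 at mid-exponential growth, gave 0 calls by edgeR, with 136 genes at an unadjusted p below 0.05. The simulated genes varied independently, with the spread that edgeR itself had estimated. They hold no deviation shared by runs of loci, so these rates need not hold for the real libraries.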

Results

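RNA was measured by sequencing in 36 libraries of the anaerobic, heat-loving bacterium Clostridium thermocellum DSM1313 (now Acetivibrio thermocellus), which ferments cellulose and its breakdown products. The parent strain lacked hpt, the gene of a purine salvage enzyme that is used as a counter-selection marker in this species. The other strains each lacked 1 further gene for a LacI-type transcription factor: Clo1313_0089 (strain del0089), Clo1313_0396 (del0396) or Clo1313_2023 (del2023). LacI-type proteins bind DNA, and many of them repress genes of sugar use until a sugar ligand releases them. Cultures grew in 1 L bioreactors at 58 °C on 5 g/L cellobiose, a disaccharide of glucose. Each was sampled at mid-exponential growth, at late-exponential growth and at the turn to stationary phase, 30 min after acid production had stopped. Each of the 12 combinations of strain and phase had 3 libraries from replicate fermentations. The question set by the series is which genes each regulator controls, and each deletion strain was therefore compared with the parent at each phase. The libraries held 11067095 to 27329402 counted reads, with a median of 18130811. The files identify genes by locus number and pair no names with these numbers, apart from 3 small RNAs, so genes are given by locus and no function is stated for them.

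The deleted genes were read first, since they check the strain labels. Clo1313_0089 had 1 to 6 reads in each of the 9 del0089 libraries, against 1971 to 5620 reads in the parent libraries. Its level in del0089 was 0.119% of the parent mean at mid-exponential growth, 0.0942% at late-exponential growth and 0.0812% at stationary phase. Clo1313_2023 had 5 to 20 reads in the del2023 libraries and lay between 0.243% and 0.674% of the parent mean. Clo1313_0396 had 3 to 56 reads in the del0396 libraries. It stood at 4.76% of the parent mean at mid-exponential growth (2.12% to 7.38% in the 3 libraries), 0.652% at late-exponential growth and 0.0283% at stationary phase. In the parent, Clo1313_0396 rose from 53.3 ± 0.891 CPM (read counts scaled to a common library size; SD, n = 3) at late-exponential growth to 2301 ± 204 CPM at stationary phase. No library went against its strain label.

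**Figure D1:**
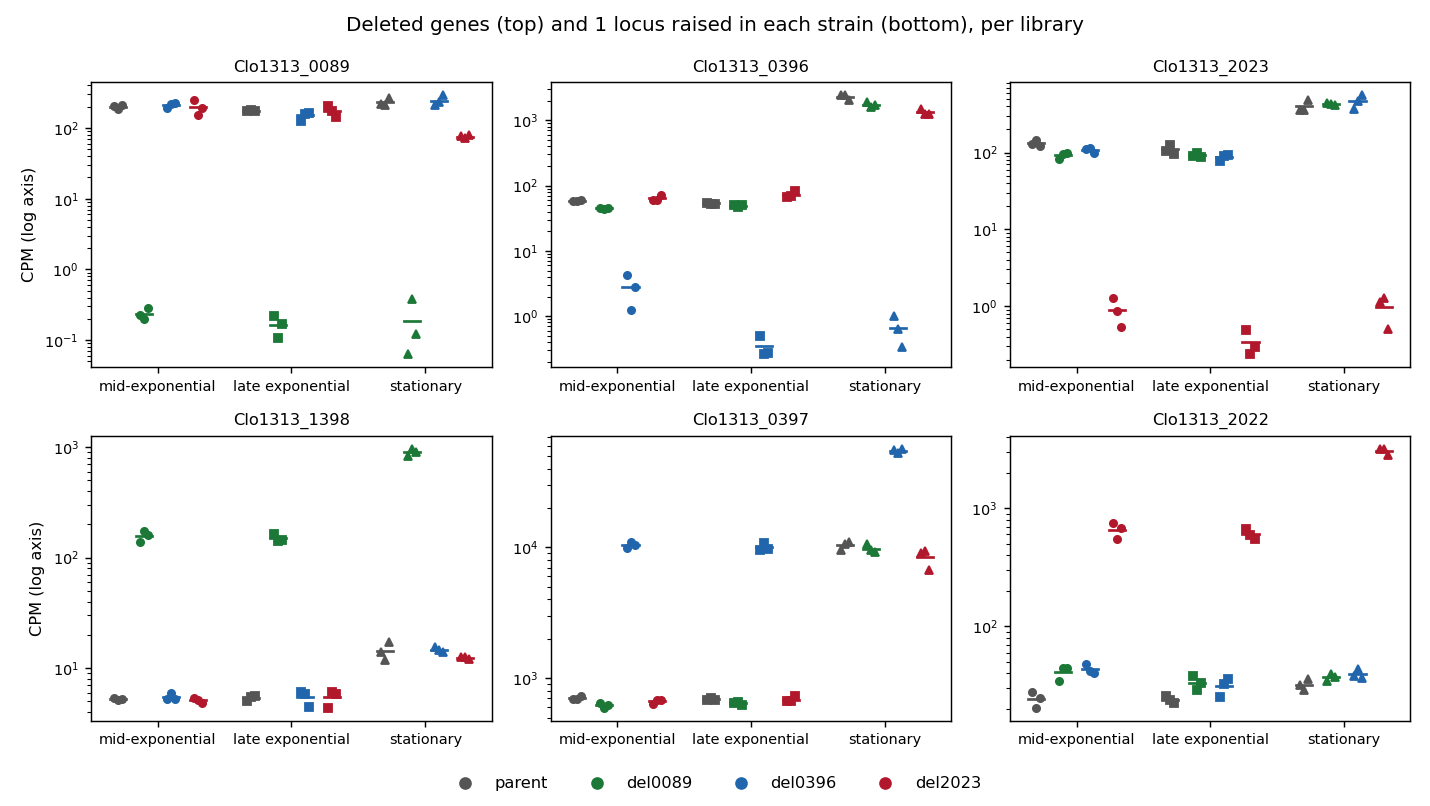
CPM per library (log axis) of the 3 deleted genes (top) and of 1 locus raised in each deletion strain (bottom), by growth phase; points are the 3 libraries of a group, horizontal bars their mean, colours the strain. The mean of each deleted gene in its own strain lies at or below 4.76% of the parent mean at each phase (single libraries reach 7.38%), and Clo1313_1398, Clo1313_0397 and Clo1313_2022 are raised in del0089, del0396 and del2023 at all 3 phases.

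Growth phase separated the libraries most. The first principal component held 69.98% of the variance and set all 12 stationary libraries apart from the 24 exponential ones. The second held 11.5% and set the 3 stationary del2023 libraries apart from the other stationary libraries. The third held 3.99%, and its highest values were those of del0089 replicate 1 (31.2) and parent replicate 2 (30.3), both at mid-exponential growth.

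**Figure D2:**
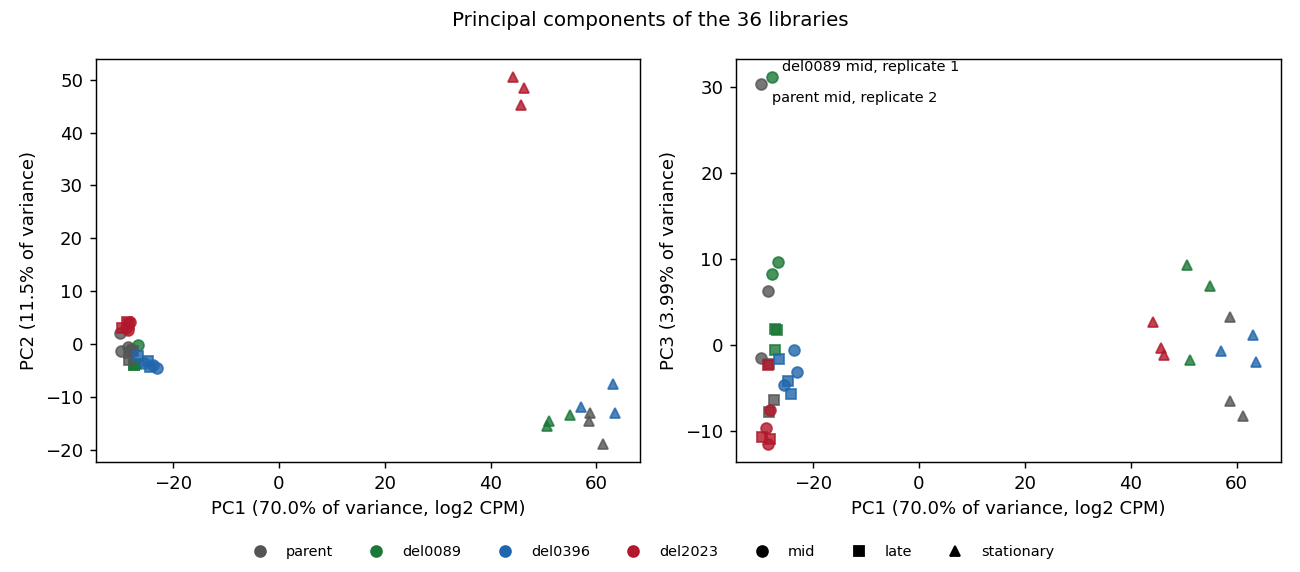
Principal components of log2 CPM over the 36 libraries; both panels have the first component (69.98% of variance) on the horizontal axis, with the second (11.5%) or the third (3.99%) on the vertical axis, colour giving the strain and symbol the phase. The stationary del2023 libraries stand alone at the top of the left panel, and the pair named in the right panel stands apart on the third component.

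In del0089 at mid-exponential growth, Clo1313_1398 rose most. It reached 158 ± 17.5 CPM (SD, n = 3) against 5.28 ± 0.0782 CPM in the parent, a 29.8-fold increase (log2 fold change 4.90 ± 0.14 SE, edgeR adjusted p = 1.8e-22). Clo1313_0399, numbered 3 loci after the regulator deleted in del0396, rose 4.45-fold (log2 2.15 ± 0.12, edgeR adjusted p = 6.0e-14). A run of 8 consecutive loci fell with a median log2 fold change of -2.21, among them Clo1313_0074 (log2 -2.54 ± 0.26, edgeR adjusted p = 1.7e-08) and Clo1313_0075 (log2 -2.38 ± 0.27, edgeR adjusted p = 2.3e-07). A run of 3 loci, Clo1313_0382 to Clo1313_0384, had a lower median of -3.20, but the libraries of the groups overlapped at all 3 loci, and without parent replicate 2 the median was 2.42 and edgeR called 0 of them (2 had an unadjusted p below 0.05). Their calls were also lost without del0089 replicate 2 (median -2.77) or replicate 3 (median -2.78), and the median was -5.60 without del0089 replicate 1. ssrA, the transfer-messenger RNA that rescues stalled ribosomes, was lower (log2 -0.95 ± 0.16, edgeR adjusted p = 1.3e-04). Of 2977 genes tested, 506 were called at an adjusted p below 0.05, 268 higher and 238 lower, and 64 of these changed at least 2-fold. Without del0089 replicate 3 the count was 336.

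At late-exponential growth the same pair of loci was higher in del0089: Clo1313_1398 rose 28.0-fold (log2 4.81 ± 0.13, edgeR adjusted p = 2.4e-22, n = 3 per group) and Clo1313_0399 rose 3.06-fold (log2 1.61 ± 0.12, edgeR adjusted p = 4.8e-11). Clo1313_2375 fell from 76.8 ± 5.11 to 20.1 ± 0.463 CPM (log2 -1.94 ± 0.14, edgeR adjusted p = 4.7e-11). Clo1313_0638, an abundant transcript at 2772 ± 207 CPM in the parent, fell to 765 ± 283 CPM (log2 -1.86 ± 0.38, edgeR adjusted p = 0.00131). ssrA was again lower (log2 -0.67 ± 0.16, edgeR adjusted p = 0.00407). The test called 562 genes, 279 higher and 283 lower (310 and 252 with DESeq2 size factors), of which 38 changed at least 2-fold. The count fell to 301 without del0089 replicate 1 and to 325 without parent replicate 3.

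At stationary phase Clo1313_1398 was 62.9-fold higher in del0089 than in the parent (899 ± 67.8 against 14.3 ± 2.68 CPM, log2 5.98 ± 0.14, edgeR adjusted p = 3.8e-24). The next locus, Clo1313_1399, was 3.29-fold higher (log2 1.72 ± 0.25, edgeR adjusted p = 6.5e-06). A run of 7 loci fell, with a median log2 fold change of -2.25, led by Clo1313_1826 (log2 -4.69 ± 0.54, edgeR adjusted p = 2.3e-07) and Clo1313_1827 (log2 -3.75 ± 0.47, edgeR adjusted p = 9.3e-07). The parent level of Clo1313_1826 itself varied widely, at 2501, 1648 and 8022 CPM in the 3 libraries, and all 3 lay above the del0089 mean of 158 ± 43.1 CPM. Without parent replicate 3 the log2 fold changes of Clo1313_1826 and Clo1313_1827 were -3.72 and -2.72, and both were still called. ssrA was lower in del0089 (log2 -0.87 ± 0.16, edgeR adjusted p = 1.7e-04). In all, 801 genes were called, 347 higher and 454 lower, and 74 changed at least 2-fold.

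In del0396 at mid-exponential growth, the loci numbered directly before and after the deleted gene rose most. Clo1313_0395 went from 36.9 ± 3.60 to 596 ± 51.8 CPM, a 16.1-fold increase (log2 4.01 ± 0.15, edgeR adjusted p = 3.3e-19, n = 3 per group). Clo1313_0397 went from 707 ± 18.1 to 10439 ± 582 CPM, a 14.8-fold increase (log2 3.88 ± 0.11, edgeR adjusted p = 2.3e-22). Among the largest decreases were those of Clo1313_0117 (log2 -5.87 ± 1.32, edgeR adjusted p = 0.00278) and Clo1313_0121 (log2 -5.67 ± 1.28, edgeR adjusted p = 0.00283). Both rest on the parent libraries, in which Clo1313_0117 stood at 156, 1340 and 23.3 CPM. Without parent replicate 2, the log2 fold changes were -3.37 and -3.17 and both calls were lost (edgeR adjusted p = 0.0560 and 0.0732), though not without both libraries that stood apart (edgeR adjusted p = 0.0142 and 0.0143). The test called 540 genes, 233 higher and 307 lower, with 81 of them at least 2-fold. That count was 255 without parent replicate 2, 350 without del0396 replicate 2, 336 without del0396 replicate 3, and 293 without both libraries that stood apart on the third component, an alternative added after the data were seen.

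At late-exponential growth Clo1313_0395 was 15.6-fold higher in del0396 (log2 3.96 ± 0.14, edgeR adjusted p = 4.5e-19, n = 3 per group) and Clo1313_0397 was 14.5-fold higher (log2 3.86 ± 0.11, edgeR adjusted p = 2.7e-22). Clo1313_0638 fell 5.69-fold, from 2772 ± 207 to 488 ± 228 CPM (log2 -2.51 ± 0.39, edgeR adjusted p = 4.8e-05). Clo1313_2375 fell 4.29-fold (log2 -2.10 ± 0.14, edgeR adjusted p = 5.7e-12). The test called 724 genes, 339 higher and 385 lower (392 and 347 with DESeq2 size factors), and 68 of them changed at least 2-fold. The count was 366 without del0396 replicate 2 and 443 when the model was fitted to the 6 compared libraries alone.

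At stationary phase Clo1313_0395 and Clo1313_0397 rose in the parent too, and their excess in del0396 was 6.34-fold (log2 2.66 ± 0.14, edgeR adjusted p = 2.7e-15) and 5.28-fold (log2 2.40 ± 0.10, edgeR adjusted p = 1.4e-17). Clo1313_0397 then stood at 54987 ± 2119 CPM in del0396 and 10406 ± 717 CPM in the parent (SD, n = 3). Clo1313_1711 fell from 33.8 ± 3.17 to 6.35 ± 1.48 CPM (log2 -2.40 ± 0.19, edgeR adjusted p = 6.9e-11), and Clo1313_1773 from 42.3 ± 1.81 to 10.7 ± 0.722 CPM (log2 -1.99 ± 0.13, edgeR adjusted p = 8.3e-13). The test called 779 genes, 350 higher and 429 lower, with 92 at least 2-fold. Fitted to the 6 compared libraries alone, it called 283.

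In del2023 at mid-exponential growth, Clo1313_2022, the locus numbered directly before the deleted gene, rose 26.9-fold, from 24.4 ± 3.72 to 659 ± 105 CPM (log2 4.75 ± 0.16, edgeR adjusted p = 3.3e-20, n = 3 per group). Clo1313_2865 rose 3.69-fold (log2 1.88 ± 0.14, edgeR adjusted p = 2.7e-11). The largest decreases after that of the deleted gene were those of Clo1313_0116 (log2 -5.78 ± 1.34, edgeR adjusted p = 0.00583) and Clo1313_0121 (log2 -5.76 ± 1.28, edgeR adjusted p = 0.00427). As in del0396, they rest on parent replicate 2, without which the log2 fold changes were -3.32 and -3.26 and both calls were lost (edgeR adjusted p = 0.112 and 0.101), though not without both libraries that stood apart (edgeR adjusted p = 0.0251 and 0.0155). Without del2023 replicate 2 the log2 fold change of Clo1313_0121 was -6.51. Both were also lost with the 6 compared libraries alone (edgeR adjusted p = 0.0666 and 0.0642). A total of 308 genes were called, 167 higher and 141 lower, and 76 changed at least 2-fold. The count was 108 without parent replicate 2, 180 without del2023 replicate 1, 199 without del2023 replicate 3, 145 without both libraries that stood apart, and 98 with the 6 compared libraries alone.

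At late-exponential growth Clo1313_2022 was 25.2-fold higher in del2023 (log2 4.65 ± 0.16, edgeR adjusted p = 5.0e-20, n = 3 per group). Clo1313_0381 was 7.52-fold higher (log2 2.91 ± 0.61, edgeR adjusted p = 0.00150), with 282, 252 and 847 CPM in the del2023 libraries and 61.2 ± 6.30 CPM in the parent. Without del2023 replicate 3 its log2 fold change was 2.12, still called. By number it lies among the 33 loci that were high in mid-exponential parent replicate 2. Their median was 17.5 CPM in late-exponential del2023 replicate 3, against 3.32 and 5.50 CPM in replicates 1 and 2. A run of 6 consecutive loci was lower at this and both other phases, and it held the largest decreases here after that of the deleted gene, those of Clo1313_1888 (log2 -3.29 ± 0.15, edgeR adjusted p = 1.9e-16) and Clo1313_1886 (log2 -3.10 ± 0.14, edgeR adjusted p = 1.3e-16). The test called 603 genes, 304 higher and 299 lower (348 and 233 with DESeq2 size factors), of which 40 changed at least 2-fold. The count was 312 without parent replicate 3 and 362 without del2023 replicate 3.

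At stationary phase del2023 differed from the parent in most of the transcriptome. Clo1313_2022 was 95.03-fold higher (3054 ± 189 against 32.1 ± 3.49 CPM, log2 6.57 ± 0.17, edgeR adjusted p = 2.0e-23). Clo1313_0107, which in the parent fell on entry into stationary phase, was 30.8-fold higher in del2023 (log2 4.94 ± 0.38, edgeR adjusted p = 1.7e-12). Clo1313_1890 fell from 706 ± 133 to 3.65 ± 0.515 CPM (log2 -7.61 ± 0.22, edgeR adjusted p = 1.1e-22), and Clo1313_1889 from 324 ± 44.5 to 2.10 ± 0.459 CPM (log2 -7.23 ± 0.28, edgeR adjusted p = 2.1e-19). ssrA was lower (log2 -0.70 ± 0.16, edgeR adjusted p = 2.9e-04), as was rnpB, the RNA of ribonuclease P (3125 ± 141 CPM against 6257 ± 221 CPM in the parent, edgeR adjusted p = 8.4e-07). The test called 2120 of 2977 genes (71.2%), 922 higher and 1198 lower, and 1114 of them changed at least 2-fold. Scaled and fitted with the 6 compared libraries alone, 1015 were higher and 1000 lower, and the median log2 fold change of all genes was -0.00 instead of -0.15. With DESeq2 size factors 970 were higher and 1145 lower, so the excess of lower genes depends on these choices. Every fit that left out 1 of the 6 libraries called between 2023 and 2069.

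**Figure D3:**
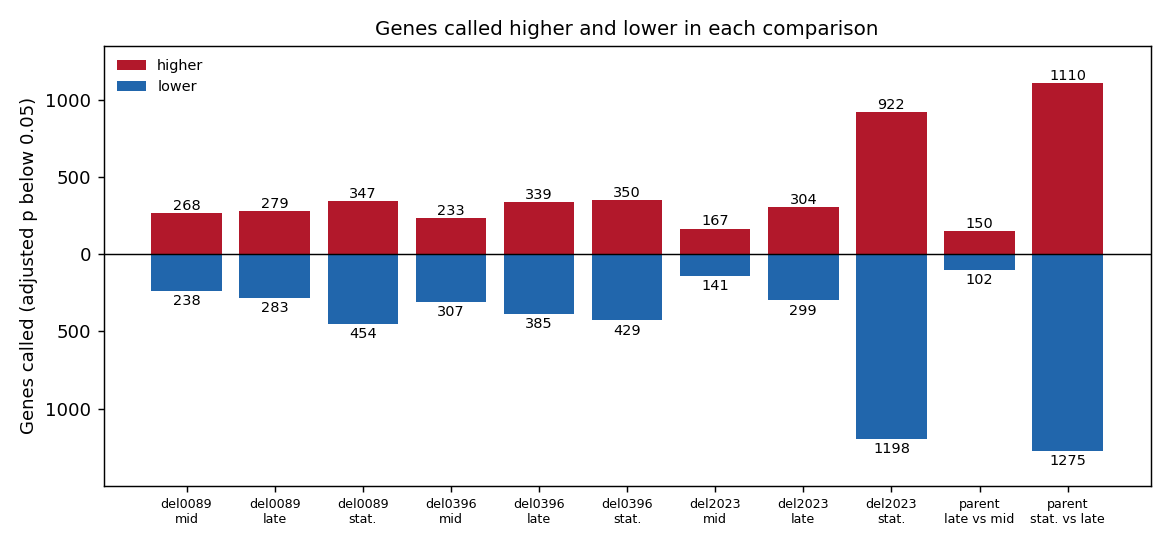
Number of genes called at an adjusted p below 0.05 in each comparison, with genes higher in the first-named group above 0 and genes lower below 0. The del2023 strain at stationary phase (922 higher, 1198 lower) and the parent's entry into stationary phase (1110 higher, 1275 lower) stand above all other comparisons shown.

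The parent's own phases give the background for these comparisons. Between mid- and late-exponential growth, Clo1313_2699 rose 3.25-fold (log2 1.70 ± 0.30, edgeR adjusted p = 0.00247, n = 3 per group) and Clo1313_2635 rose 2.90-fold (log2 1.53 ± 0.27, edgeR adjusted p = 0.00247). The largest decreases, those of Clo1313_0374 (log2 -7.52 ± 1.76, edgeR adjusted p = 0.0101) and Clo1313_0375 (log2 -7.18 ± 1.62, edgeR adjusted p = 0.00980), came from 1 library. Clo1313_0374 stood at 294 CPM in mid-exponential parent replicate 2 and at 1.51 and 0.740 CPM in replicates 1 and 3. Without that library the log2 fold changes were -1.11 and -0.98, and both calls were lost (edgeR adjusted p = 0.724 and 0.684). They were also lost with the fermenter as a block (edgeR adjusted p = 0.0884 and 0.0709), without late-exponential replicate 3 (edgeR adjusted p = 0.0593 and 0.0573) and with the 6 compared libraries alone (edgeR adjusted p = 0.103 for both). The test called 252 genes, 150 higher and 102 lower, 60 of them at least 2-fold; with DESeq2 size factors the split was 107 higher and 129 lower. The count was 28 without mid-exponential replicate 2, 106 without mid-exponential replicate 1, 145 without late-exponential replicate 1, 46 without late-exponential replicate 3, 121 with the 6 compared libraries alone, and 61 without both libraries that stood apart.

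**Figure D4:**
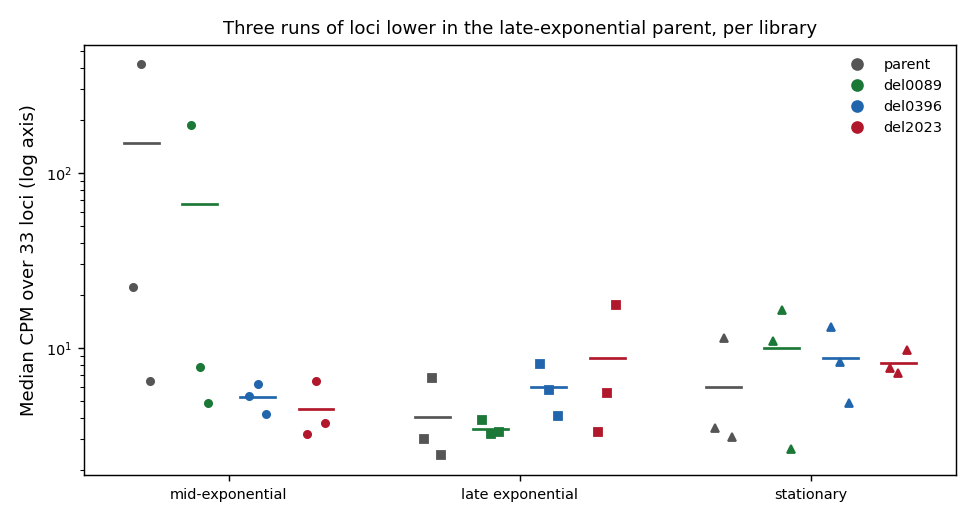
Median CPM (log axis) over 33 loci in 3 runs that were lower in the late-exponential than in the mid-exponential parent, for each of the 36 libraries; points are libraries, horizontal bars group means, colours strains. Mid-exponential parent replicate 2 (418 CPM) and del0089 replicate 1 (188 CPM) lie above all other libraries, the next of which is at 22.2 CPM.

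Entry into stationary phase changed most genes of the parent. Clo1313_1826 rose 97.8-fold (log2 6.61 ± 0.59, edgeR adjusted p = 1.8e-11, n = 3 per group) and Clo1313_1346 rose 90.5-fold, from 36.8 ± 6.21 to 3331 ± 704 CPM (log2 6.50 ± 0.32, edgeR adjusted p = 1.7e-17). Clo1313_0107 fell from 530 ± 63.0 to 14.0 ± 0.975 CPM (log2 -5.24 ± 0.39, edgeR adjusted p = 2.8e-13), and the next locus, Clo1313_0108, fell with it (log2 -4.94 ± 0.95, edgeR adjusted p = 2.4e-05). Without stationary replicate 3 the log2 fold change of Clo1313_1826 was 5.64, and without stationary replicate 2 that of Clo1313_0108 was -6.16, both still called. The small RNAs rose: ssrA (log2 2.48 ± 0.17, edgeR adjusted p = 4.2e-14), rnpB (log2 2.12 ± 0.16, edgeR adjusted p = 2.2e-13) and ffs, the RNA of the signal recognition particle (log2 1.78 ± 0.33, edgeR adjusted p = 1.9e-05). The test called 2385 genes, 1110 higher and 1275 lower (1200 and 1185 with DESeq2 size factors), of which 1536 changed at least 2-fold. The median log2 fold change of all genes was -0.10 with TMM scaling and 0.02 with DESeq2 size factors, so each fold is relative to that shift.

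Whether a strain's effect changed with growth phase was tested directly. It did for 373 genes in del0089, 576 in del0396 and 1951 in del2023, out of 2977. The deleted genes were left out of the ranking by interaction p that follows. The smallest p in del0089 was that of Clo1313_2747, which was higher than the parent at mid-exponential growth (log2 1.40 ± 0.14) and lower at stationary phase (log2 -0.65 ± 0.14; edgeR interaction adjusted p = 4.5e-07). In del0396 it was that of Clo1313_0397 (log2 3.88 against 2.40, edgeR interaction adjusted p = 2.4e-09). In del2023 it was that of Clo1313_1891, in the same run of 6 loci as Clo1313_1886, with a log2 fold change of -1.59 ± 0.11 at mid-exponential growth and -6.24 ± 0.14 at stationary phase (edgeR interaction adjusted p = 4.6e-20). Called in the same direction at all 3 phases were 138 genes in del0089 (77 higher, 61 lower), 91 in del0396 (50 higher, 41 lower) and 80 in del2023 (45 higher, 35 lower). These genes were ranked by the largest of their 3 adjusted p-values, smallest first, without the strain's own deleted gene. The first were Clo1313_1398 and Clo1313_2940 (log2 0.80, 0.87 and 0.85) in del0089. In del0396 they were Clo1313_0397 and Clo1313_0395, and in del2023 Clo1313_2022 and Clo1313_1886. Of the 138, 91 and 80 genes, 11, 9 and 45 also had an effect that changed in size with phase by the interaction test. Independent calls would give 2.93 higher and 3.45 lower, 3.12 and 5.72, and 5.28 and 5.70 genes called in the same direction at all 3 phases in these strains. The 3 phases of a strain share no libraries, though by the protocol they share fermenters.

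The loci numbered within 5 of each deleted gene formed 3 lists of 10 fixed in advance. In del0396 its own list had 2 members higher and 3 lower at mid-exponential growth, 2 and 0 at late-exponential growth, and 3 and 2 at stationary phase. Adjusted over the list alone these were 3 and 3, 2 and 0, and 3 and 2. Camera with a preset correlation placed the list above other genes at the 3 phases (adjusted p = 0.0301, 0.0143 and 0.0328), and with an estimated correlation it did not (adjusted p = 0.279, 0.275 and 0.279). The 3 members lower at mid-exponential growth lie in a run that was high in parent replicate 2, and leading the higher ones were Clo1313_0395 and Clo1313_0397. In del2023 its own list had 2 members higher and 0 lower, 3 and 0, and 4 and 4 in phase order; adjusted over the list alone, these were 3 and 0, 3 and 0, and 4 and 4. Camera gave adjusted p = 0.0133, 0.0301 and 0.742 with the preset correlation and adjusted p = 0.0595, 0.112 and 0.781 with an estimated correlation. Clo1313_2022 led this list at every phase, and the locus directly after the deleted gene was called higher at mid-exponential growth (log2 0.48) and lower at stationary phase (log2 -1.57). In del0089 its own list had 2 higher and 1 lower, 2 and 1, and 4 and 1, with the same counts adjusted over the list alone and no call by camera (adjusted p = 0.753, 0.742 and 0.373). The locus directly before the deleted gene was higher at all 3 phases (log2 0.69, 0.50 and 0.94). Over all 33 tests of list and comparison, camera made 7 calls with the preset correlation and 0 with an estimated one, with which 5 had an unadjusted p below 0.05. The 2 calls on other strains' lists were those of the Clo1313_0396 list, lower in del2023 at mid-exponential growth (adjusted p = 0.0133, or 0.275 with an estimated correlation) and higher in the parent at stationary phase than at late-exponential growth (adjusted p = 0.0328, or 0.279 with an estimated correlation). In del2023, 3 of the 4 members called lower lie in the run that was high in parent replicate 2. Without that library edgeR called 0 members of the list (4 had an unadjusted p below 0.05), and camera gave adjusted p = 0.0254 with the preset correlation and adjusted p = 0.243 with an estimated one. Without it camera also placed the list above other genes in mid-exponential del0089, with the same adjusted p of 0.0254, or 0.243 with an estimated correlation.

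**Figure D5:**
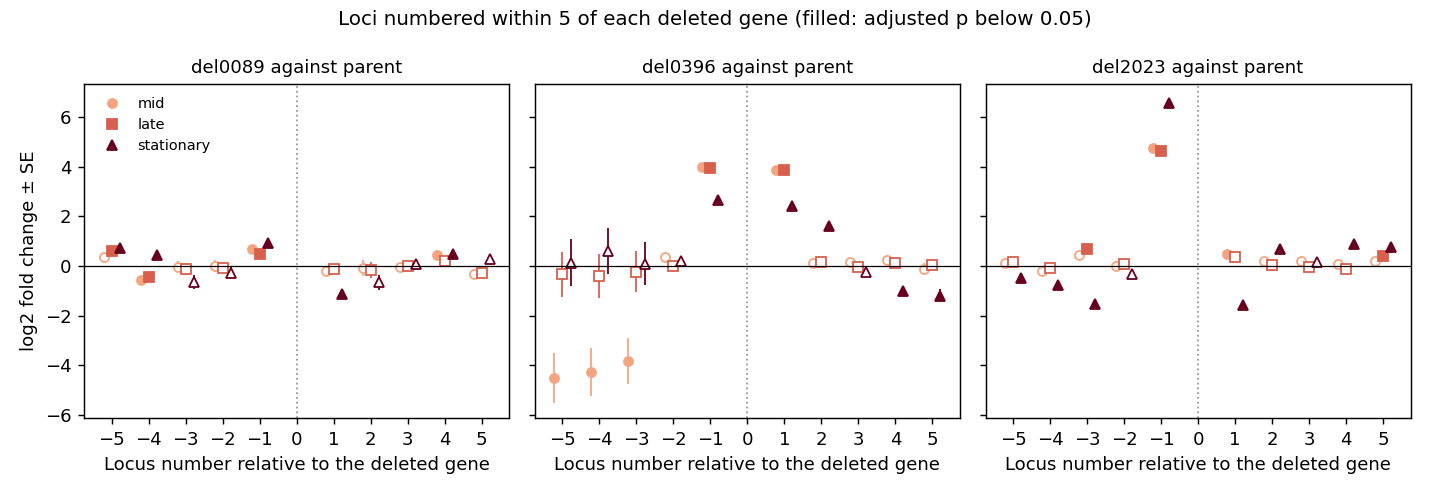
log2 fold change ± SE (n = 3 per group) of the loci numbered within 5 of each deleted gene, in the strain lacking that gene against the parent; symbols and shades give the phase and filled symbols an edgeR adjusted p below 0.05. Both loci next to Clo1313_0396 are higher in del0396 (log2 2.40 to 4.01), the locus before Clo1313_2023 is higher in del2023 (log2 4.65 to 6.57), and that before Clo1313_0089 rises by at most log2 0.94 in del0089.

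The deletion strains shared many calls. At mid-exponential growth, del0089 and del0396 had 163 genes called in the same direction and 13 in opposite directions, del0396 and del2023 had 129 and 19, and del0089 and del2023 had 43 and 45. Independent lists would share 45.3, 27.5 and 26.2 genes in the same direction. At late-exponential growth the same-direction counts were 317, 245 and 127 against 68.2, 73.1 and 56.8, and at stationary phase 367, 475 and 424 against 106, 280 and 290. In opposite directions there were 1, 11 and 33 genes at late-exponential growth and 10, 134 and 189 at stationary phase, in the same order of pairs. All 3 strains shared 28 genes at mid-exponential growth (8 higher, 20 lower), 99 at late-exponential growth (46 higher, 53 lower) and 240 at stationary phase (85 higher, 155 lower). The mid-exponential counts rest in large part on parent replicate 2. Without it the pairs shared 74, 22 and 18 genes in the same direction (independent lists: 15.5, 4.39 and 6.80), and all 3 strains shared 4. Without late-exponential parent replicate 3 the pairs shared 185, 124 and 45 genes, and all 3 strains 35. Leaving out 1 library at a time, all 3 strains shared 4 to 57, 35 to 122 and 187 to 253 genes in phase order. All strains were compared with the same 3 parent libraries per phase, which cannot be divided, so part of the excess may come from them. Across genes, the covariance of the log2 fold changes was 0.0419 to 0.314 for the 9 pairs of strains, against 0.0245 to 0.0357 for simulated strains without any change, and was above the simulated value for all 9 pairs. The correlation was 0.267 to 0.798 against a simulated 0.480 to 0.544, and was below the simulated value for 5 of the 9 pairs, among them all 3 at stationary phase. The highest covariance and the highest correlation were both those of del0396 and del2023 at mid-exponential growth, and were not recomputed without parent replicate 2. The simulated genes varied independently, whereas runs of loci were high together in that library, so the simulation does not hold that shared deviation. Genes are not independent replicates in this comparison.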

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

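All 6 tests of explanations in this part were chosen after the results were seen, while the tests of whether an effect changed with phase were planned.

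The difference between a deletion strain and the parent changed with growth phase for 373 genes in del0089, 576 in del0396 and 1951 in del2023 (edgeR, adjusted p below 0.05). In del0089, Clo1313_2747 moved by -2.05 on the log2 scale from mid-exponential growth to stationary phase (log2 fold change at stationary phase minus that at mid-exponential growth), and Clo1313_1213 by 1.77. In del0396, Clo1313_0397 moved by -1.48 and Clo1313_1773 by -1.96. In del2023, Clo1313_1891 moved by -4.65 and Clo1313_1513 by 3.58. The R-numbered rows, outside every test, held a median of 0.453% of a library's reads.

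The first pattern is the reach of the del2023 deletion at stationary phase, with 2120 genes called against 801 in del0089 and 779 in del0396. The choice between TMM and DESeq2 size factors is an unlikely cause, since the latter left 2115 calls. Both scalings take most genes as unchanged, so a scaling error common to both was not tested. Libraries of another strain under this label are ruled out by Clo1313_2023, at no more than 0.316% of the parent mean in any of the 3 libraries. Sampling between the parent's late-exponential and stationary states would, as the whole cause, keep genes within the parent's range if they changed steadily. In 55.2% of the 2119 called genes other than the deleted gene, all 3 del2023 libraries lay outside all 6 parent libraries of both phases. The counts were 235 of 800 in del0089 and 359 of 778 in del0396. No parent library lies between these phases, and genes may peak or dip there, so such sampling cannot be excluded as the whole cause. Over the called genes the difference had a slope of -0.343 to -0.304 on the late-to-stationary change of del0089 and del0396. That change took up 11.26% to 13.02% of the variance of the difference, which leaves earlier sampling open for part of it. The slope was negative in all 3 libraries, which argues against a later sample in which the same changes had gone further. The 3 slopes share the parent stationary mean, the late-to-stationary change and the called genes, so their signs are not independent. Later states of another kind were not sampled. An effect of losing the regulator may also account for the difference.

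The second pattern is a set of 33 loci in 3 runs, among them Clo1313_0374, whose median level was 418 CPM in mid-exponential parent replicate 2 and 188 CPM in del0089 replicate 1, against a median of 5.62 CPM over the other 34 libraries. RNA of another library of the series mixed into mid-exponential parent replicate 2 would need a source with a higher level. That parent library itself held 2.23 times the highest level elsewhere. RNA of that parent library mixed into mid-exponential del0089 replicate 1 would have to make up 44.9% of it. However, Clo1313_0089 stood there at 0.115% of the parent mean. The design names no difference between these fermentations and their replicates, so no biological explanation was tested. A state of these cultures at the time of sampling may remain as an explanation, as may RNA from outside the series.

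The third pattern is the run of 6 consecutive loci from Clo1313_1886 on, all called lower in del2023 at all 3 phases, with a median log2 fold change of -3.09, -2.76 and -6.82 in phase order. A further deletion that removed these loci would leave only stray reads. At mid-exponential growth their level was 11.8% of the parent (9.95% to 15.3% in the 3 libraries), above the 0.674% left of the deleted gene itself and the 4.76% (2.12% to 7.38%) left of Clo1313_0396 in del0396. Loss of the regulator stays open as a hypothesis, and a direct effect on these loci could not be told from an indirect one.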

How the results depend on the processing

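Of the alternatives reported here, the fits without both libraries that stood apart and the fermenter block in the interaction tests were chosen after the results were seen, as were the tests on other splits of the samples. All 14 counts stayed within 1.5 times the reported value with DESeq2 size factors, the DESeq2 test, no filter on low counts, the R-numbered rows kept, counts thinned to the smallest library, and the block. With a minimum change of 2-fold, which by its construction calls fewer genes, the counts in phase order were 64, 38 and 74 in del0089, 81, 68 and 92 in del0396, 76, 40 and 1114 in del2023, and 60 and 1536 in the parent. The interaction counts were then 99, 146 and 1172. With only the 6 libraries compared, the counts were 443 in late-exponential and 283 in stationary del0396, 98 in mid-exponential del2023 and 121 in the late- against mid-exponential parent, and the cause was not tested. Without both libraries that stood apart, they were 293 in mid-exponential del0396, 145 in mid-exponential del2023 and 61 in the late- against mid-exponential parent, from fewer samples. Camera made 0 calls with an estimated correlation, and 7 with the preset one.

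Leaving out 1 library at a time gave 336 to 546 genes in mid-exponential, 301 to 575 in late-exponential and 600 to 692 in stationary del0089. It gave 255 to 426, 366 to 848 and 617 to 777 in del0396, 108 to 255, 312 to 494 and 2023 to 2069 in del2023, and 28 to 210 and 2298 to 2338 in the parent. The interaction counts were 270 to 450, 439 to 765 and 1842 to 1955. Of 1022 values of named genes that had an adjusted p under an alternative, 1005 kept their direction and their side of the threshold. Most of these genes were named for large changes or small p-values in the same libraries. Their agreement was therefore likely beforehand and does not speak for the called genes at large. Of the others, 17 kept only the direction and 0 changed direction. Among the 17 is ffs in stationary del2023 (log2 -0.97, edgeR adjusted p = 0.00963), with an adjusted p of 0.0569 without del2023 replicate 1. The others concern Clo1313_0116, Clo1313_0117, Clo1313_0121, Clo1313_0374 and Clo1313_0375.

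Replicate numbers were taken to pair the samples for the phase comparisons, from the protocol. Same-numbered parent libraries of successive phases had correlations of 0.0340 to 0.292 and 0.0405 to 0.124, not all above 0.1. Between stationary and mid-exponential del0089 they ran from -0.454 to 0.489. The fermenter block gave 224 and 2388 genes in the parent and 373, 570 and 1942 in the interaction tests. The numbers were also taken as pairs for stationary del0089 (804 genes with the block) and del0396 (779), by their correlations. The block ended the calls of Clo1313_0374 and Clo1313_0375 and no other call of a named gene. Elsewhere the samples share only a number and the run of library codes that goes with it (lowest correlation of same-numbered libraries -0.647, highest 0.510), and the block gave 490 and 553 genes in mid- and late-exponential del0089, 530 and 722 in del0396, and 298, 573 and 2120 in del2023. With the replicate number as a block over all groups, the interaction counts were 359, 562 and 1939.

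Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. In all 14 comparisons no split but the real one gave as many calls as the real value. Every other split mixes libraries of both groups, so a difference of any source widens the spread within them. Few calls in those splits therefore do not tell the source of the difference. The real value and the highest other were 506 and 53, 562 and 0, and 801 and 1 in del0089 in phase order. They were 540 and 0, 724 and 47, and 779 and 183 in del0396, 308 and 28, 603 and 0, and 2120 and 6 in del2023, and 252 and 36, and 2385 and 0 in the parent. For the interaction tests they were 373 and 29, 576 and 5, and 1951 and 0. Thinning every library to the smallest total left 463 to 766 calls in del0089, 511 to 750 in del0396, 283 to 2075 in del2023, and 201 and 2346 in the parent. Whether deeper sequencing would call more genes was not tested.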

Other observations

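The counts in runs without 1 library were chosen after the results were seen. Changed genes lay side by side along the locus numbers. Of the genes changed at least 2-fold in del2023 at mid-exponential growth, 81.6% (62 of 76) lay in runs of at least 3 consecutive loci that moved the same way. In del0396 at mid-exponential growth the share was 66.7% (54 of 81), and in the late- against mid-exponential parent it was 66.7% (40 of 60). These 3 shares rest in large part on mid-exponential parent replicate 2, since 30, 27 and 33 of the genes in runs belong to the 33 loci that were high in it. Without that library 11 of 22 genes (50.0%) lay in runs in del2023, 11 of 34 (32.4%) in del0396 and 0 of 15 in the late- against mid-exponential parent. In the other strain comparisons except del2023 at stationary phase, the share was 23.0% to 35.9%. Over 1000 shuffles of the locus order, these 9 strain and phase comparisons other than del2023 at stationary phase and the parent's entry into stationary phase gave a mean of at most 0.094 genes in runs. Those 2 comparisons had 563 of 1114 and 911 of 1536 genes in runs, against shuffled means of 105 and 245.

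In del0089 and del0396 a run of 8 loci that includes Clo1313_0074 and Clo1313_0075 was lower at mid-exponential growth, with a median log2 fold change of -2.21 and -1.44. The median over the same 8 loci was -1.61 at late-exponential growth and -0.87 at stationary phase in del0089 (8 and 7 loci called lower), and -1.14 and -1.59 in del0396 (7 and 8 called lower). In del2023 it was -0.29, -0.30 and 0.58 in phase order, with 5 loci called higher at stationary phase.

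The parent's own stationary phase moved some of the same loci as a deletion. Clo1313_0395 and Clo1313_0397, raised in del0396, rose in the parent from late-exponential growth to stationary phase by 5.33 ± 0.15 and 3.92 ± 0.11 on the log2 scale (SE, edgeR adjusted p = 1.8e-22 and 4.8e-23, n = 3 per group), while Clo1313_0396 itself rose as well. Clo1313_1398, raised in del0089, rose by 1.42 ± 0.13 (edgeR adjusted p = 2.7e-11), and Clo1313_2022, raised in del2023, by 0.43 ± 0.14 (edgeR adjusted p = 0.00718). In mid-exponential del0089 and del0396, Clo1313_2022 was also higher than in the parent, by 0.75 ± 0.14 and 0.84 ± 0.14 (edgeR adjusted p = 3.1e-04 and 2.0e-04).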
